A study of Mus musculus with 16 samples.

How the data were processed

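Goblet cells and the remaining epithelial cells of RedMUC298trTg mice aged 6 to 8 weeks were profiled by bulk RNA sequencing. This line carries an mCherry-tagged MUC2 reporter, so that mucus-producing cells fluoresce red. Per the labels' protocols, epithelium was stripped from the distal colon and from section 8 of the small intestine with EDTA, digested with collagenase and DNase, and sorted alive by the presence or absence of mCherry. RNA came from MinElute columns for the mCherry-positive cells and from Mini columns for the mCherry-negative cells, so column type and cell type cannot be told apart. The libraries were stranded, made from total RNA after removal of ribosomal RNA, and read from both ends. DC is the distal colon and Si8 is section 8 of the small intestine; goblet sort means mCherry-positive cells and other sort means mCherry-negative epithelial cells.

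Read counts per gene were deposited in a table for each region, and another deposited table held the counts of all 16 libraries divided by size factors, a normalized signal. Per the submitters' processing notes, the tools named were FastQC 0.11.2, STAR 2.4.0f, HTSeq 0.6.1p1 and DESeq2 1.14, with the mm10 genome build; their parameters, including the strand setting of the counting, are not given in the sources used here. Each count table listed 46882 genes. The normalized signal deposited by the authors covered 32446 of them, and each of the 14436 others had at most 1 count over the 16 libraries. Multiplied by the size factor of its library, 100% of the 519072 normalized values was whole and equal to the deposited count, within 0.001 of the larger of 1 and the value. The counts were therefore used for every test. 4 entries whose symbol occurred more than once were left out, and 27 symbols that a spreadsheet had turned into dates are not named. No column of per-sample values was left unused.

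The mitochondrially encoded genes had 0 counts in all 8 DC libraries and took part of the counts in all 8 Si8 libraries, so the tables of the 2 regions differ in these genes. Transcripts of the GENCODE M21 annotation, whose build GRCm38 is mm10, were compared with the mitochondrially encoded ones by blastn to find nuclear genes of mitochondrial sequence: a match of at least 100 bp, at least 90% identity and at least 50% of the transcript. Coordinates come from the same annotation.

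Groups were taken from the labels: 4 libraries each of DC goblet, DC other, Si8 goblet and Si8 other cells. The labels do not say which libraries come from separate animals, and p-values then measure only the spread between these samples, which may be technical. The test, the libraries in each fit, the gene lists, the rule for named genes and most alternatives were set before the data were examined. Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr by group, 1 fit over the 4 groups with no covariate, robust quasi-likelihood dispersions and a quasi-likelihood F test per contrast. 16001 genes passed the filter. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and a second count also asked for an absolute log2 fold change of at least 1. The common biological coefficient of variation was 0.128 and the median prior degrees of freedom were 6.97. The 5 contrasts were goblet against other cells in DC, the same in Si8, DC against Si8 in goblet cells, DC against Si8 in other cells, and the difference of the goblet effect between the regions. A standard error was taken as the absolute log2 fold change over the square root of F. CPM values use the TMM-scaled totals.

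33 gene lists with 459 entries were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation. The rotation test fry was also run, and its values are not printed. A list needed 3 tested genes, which left 32; the erythroid list had fewer. The lists covered mucus components, secretory transcription factors, mucin O-glycosylation, endoplasmic reticulum (ER) folding, ER to Golgi transport, granule exocytosis, ion and fluid secretion, brush border, small intestinal digestion, ileal bile acid and cobalamin uptake, colonocyte absorption, surface differentiation, fatty acid oxidation, cholesterol synthesis, xenobiotic metabolism, antimicrobial proteins, microbial sensing, MHC class II, interferon response, posterior patterning, small intestinal transcription factors, proliferation, early response and dissociation stress, mitochondrially encoded genes, and markers of stem, Paneth, deep crypt secretory, enteroendocrine, tuft, intraepithelial lymphocyte, B, plasma and myeloid, stromal and erythroid cells.

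The named genes follow a rule. Per contrast it takes the 6 largest and the 6 smallest log2 fold changes among called genes with a mean of at least 10 CPM in the higher group and no overlap between the 4 libraries of one group and those of the other; the overlap part is dropped for the difference of effects. Predicted genes, ribosomal RNA, pseudogenes and immune receptor segments are left out. It adds up to 3 called members per list with the largest absolute log2 fold change and a mean of at least 5 CPM in the higher group, and 14 genes in every contrast: Muc2, Fcgbp, Clca1, Zg16, Tff3, Agr2, Spdef, Atoh1, Best2, Mxd1, Vil1, Krt20, Fabp6 and Car1. 249 genes were so chosen. Mean levels of cell type markers, log2(CPM + 0.5), were compared by two-sided exact permutation tests of 4 against 4 libraries, whose smallest possible p is 0.0286, adjusted over 20 tests.

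Library totals ran from 11.9 to 18.5 M counts in DC and from 30.8 to 41.1 M in Si8. A group whose libraries are all at 0 was set to a floor of 3 counts over its summed totals, 0.0442 CPM in DC other, 0.0413 in DC goblet, 0.0231 in Si8 other and 0.0209 in Si8 goblet cells, and the fold is then a lower bound. With 1 to 3 counts in a group, the ratio sets the other group's mean CPM against these counts over the group's summed totals, with the 95% Poisson interval of the low count. Floors and intervals cover counting error only. On counts simulated from these libraries, with 15689 genes, the DC goblet comparison recovered 67.2% of the genes changed 1.5-fold, 86.6% of those changed 2-fold and 93.9% of those changed 4-fold. For the difference of effects, with 15765 genes, the shares were 25.4%, 64.2% and 97.0%. Only 67, 67 and 66 genes were so changed, all with a mean of at least 1 CPM. Far more genes were called in the data, so the shares hold for the simulated setting only. Unchanged genes were from 2.53% to 6.15% of those called over the contrasts. Other scalings (DESeq2 size factors, library totals, the 20 most abundant genes or the mitochondrially encoded genes left out), filters, tests (DESeq2 1.42.0, limma-voom, limma on the deposited normalized values), thresholds, a replicate block, fits of single comparisons and fits without each library were tried. 4 more were chosen after seeing the data: whole reads recovered from the normalized signal, mitochondrial and matching nuclear genes left out, Si8 libraries thinned to the mean DC total, and Paneth genes and defensins left out.

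Muc2 counts may hold reads of the transgene, which cannot be separated here. Near-identical genes (the Defa family, Reg3b and Reg3g, Mcpt1 and Mcpt2, Hspa1a and Hspa1b) share reads and their single values are uncertain, as are those of overlapping or antisense genes.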

Results

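The data were 16 bulk RNA libraries of sorted intestinal epithelium, 4 in each of 4 groups: goblet cells and the other epithelial cells of the distal colon (DC), and the same sorts of section 8 of the small intestine (Si8). The design asks which genes goblet cells express above the epithelium around them, and how goblet cells of the colon differ from those of the small intestine. Total counts per library ranged from 14.9 to 17.7 M in DC other cells and from 11.9 to 18.5 M in DC goblet cells. In Si8 they ranged from 30.8 to 41.1 M in other cells and from 37.4 to 40.5 M in goblet cells. The 10 most abundant genes took 8.95% ± 0.748 of the counts in DC other cells, 9.27% ± 0.229 in DC goblet cells, 14.7% ± 1.44 in Si8 other cells and 22.5% ± 4.86 in Si8 goblet cells (SD, n = 4 libraries each). Levels are mean CPM ± SD over the 4 libraries of a group, and changes are log2 fold changes ± SE with adjusted p from edgeR's quasi-likelihood test over 16001 genes. Principal components were taken over the 1000 tested genes with the largest variance between libraries. The first held 74.5% of the variance of these genes and separated the regions, and the second held 19.1% and separated goblet from other cells.

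The sort separated goblet cells from the rest in both regions. Muc2, the gel-forming mucin whose reporter defined the sort, stood at 10033 ± 576 CPM in DC goblet cells against 39.9 ± 6.71 in DC other cells, and at 39440.0 ± 17348 against 54.1 ± 26.9 in Si8. On the log2(CPM + 0.5) scale, Muc2, Paneth cell markers and deep crypt secretory cell markers were higher in every goblet library than in every other-cell library of their region (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.0381). In DC the Paneth means were −0.31 in goblet and −0.81 in other cells, near the value of 0 counts on this scale. Markers of enteroendocrine cells, intraepithelial lymphocytes, B, plasma and myeloid cells and stromal cells were lower in all 4 goblet libraries of both regions, with the same p. Means of the lymphocyte, B, plasma and myeloid markers in DC were low in both sorts, from −0.64 to 0.10. Stromal means were low in both sorts of both regions, from −0.62 to 0.02. Stem cell markers were higher in the Si8 goblet sort by 0.60 but did not pass in DC, where the exact permutation p was 0.229 (adjusted 0.254). Tuft cell markers did not pass in DC (exact permutation p = 0.857, adjusted 0.886) or in Si8 (p = 0.0571, adjusted 0.0714). Erythroid markers did not pass either, with exact permutation p of 0.886 in DC and 0.143 in Si8 (adjusted 0.886 and 0.168).

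**Figure D1:**
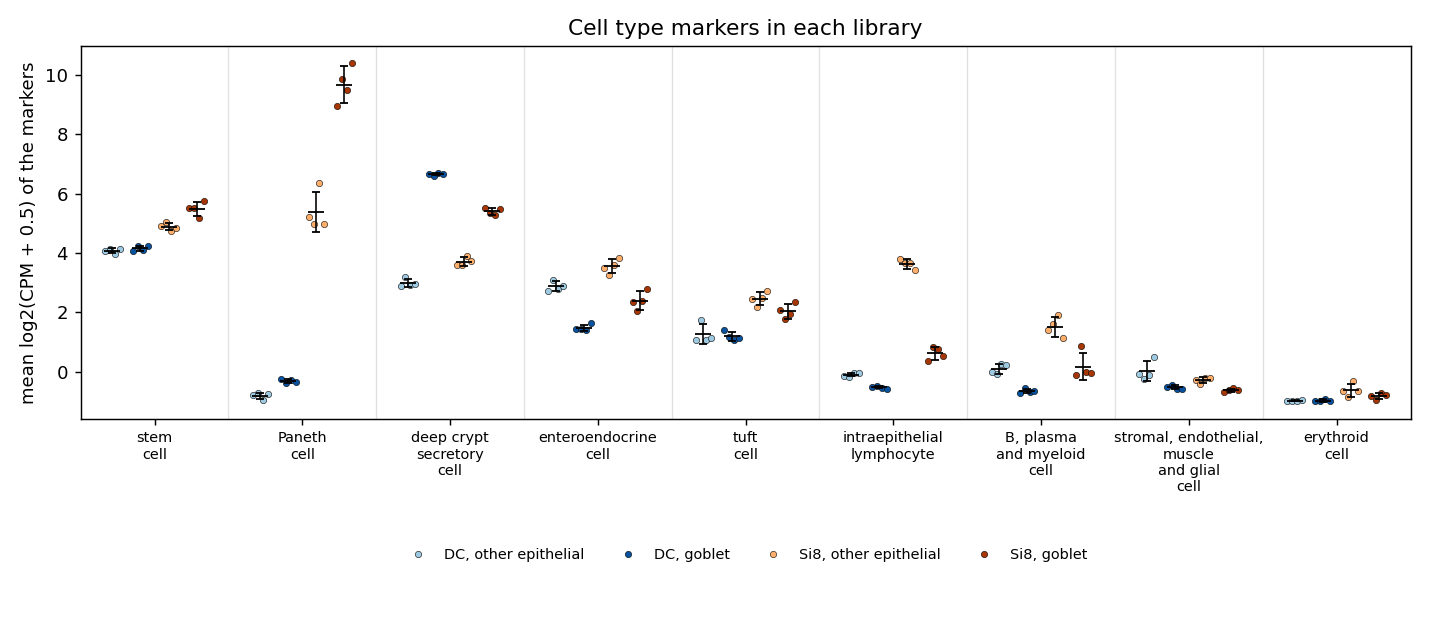
Mean log2(CPM + 0.5) of each cell type's marker genes in the 4 groups; each point is a library and the bars are the mean and SD of 4 libraries. Paneth markers average 9.67 in Si8 goblet and 5.38 in Si8 other libraries.

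In the distal colon, goblet cells were marked by mucus proteins, the secretory lineage factors that specify them, and glycosyltransferases. Fcgbp, which encodes a mucus protein that binds the Fc part of IgG, reached 14730.0 ± 961 CPM against 74.0 ± 10.1, a rise of 7.64 ± 0.33 (199-fold). Atoh1, the master regulator of the secretory lineage, rose 166-fold, from 1.86 ± 0.195 to 309 ± 35.1 CPM. Best2, a bicarbonate-permeable anion channel, rose 348-fold from 0.604 ± 0.291 to 212 ± 43.7 CPM. Genes that fell include the sodium-proton exchanger Slc9a3 (206 ± 38.0 to 3.28 ± 0.794 CPM, 63.0-fold) and the water channel Aqp8 (1015 ± 44.7 to 19.6 ± 4.33 CPM, 52.1-fold). edgeR called 8911 of 16001 genes, 4444 higher and 4467 lower in goblet cells, of which 1465 and 2155 changed by a log2 of at least 1.

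All 10 mucus components were higher in DC goblet cells. The metalloprotease-like Clca1 rose 83.3-fold, the lectin-like Zg16 84.6-fold, the trefoil peptide Tff3 73.3-fold and the disulphide isomerase Agr2, which mucin folding requires, 19.8-fold. Retnlb, an antibacterial protein of goblet cells, had at most 3 counts in all DC other libraries together and a count ratio of 566 (95% counting interval 194 to 2744). The list passed with camera (adjusted p = 4.3e-14, and adjusted p = 0.0212 with an estimated correlation), but Muc2 is tied to the reporter of the sort. Of 12 secretory transcription factors 11 were higher and 1 lower (adjusted p = 9.7e-17, and 0.00318 with an estimated correlation), with Gfi1 up 119-fold and Spdef, needed for goblet maturation, up 109.5-fold. Mucin O-glycosylation had 18 of 24 genes higher and 5 lower (adjusted p = 2.3e-14, and 0.0137 with an estimated correlation); the sulfotransferase Gal3st2 rose 123-fold, and B3gnt6, the core 3 synthase, rose 45.6-fold. A4gnt, which caps glycans with N-acetylglucosamine, rose 371-fold, and the tryptase Tpsg1 374-fold.

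The secretory machinery rose with the mucins in DC. In ER folding, 25 of 26 genes were higher (adjusted p = 1.4e-14, and 0.0212 with an estimated correlation), among them the stress sensor of mucous epithelia Ern2 (9.18-fold) and the disulphide isomerases Pdia5 (9.88-fold) and Pdia6 (4.12-fold). In ER to Golgi transport, 24 of 25 were higher (adjusted p = 1.4e-20, and 0.0212 with an estimated correlation), led by the retrieval receptor Kdelr3 (13.8-fold), with the cargo receptor Lman1 at 5.62-fold and the coat protein Sec24d at 4.69-fold. Granule exocytosis had 12 of 17 genes higher and 3 lower (adjusted p = 8.1e-09, and adjusted p = 0.114 with an estimated correlation), including the calpain Capn9 (169-fold), the synaptotagmin-like Sytl2 (44.5-fold) and its partner Rab27a (12.5-fold). Deep crypt secretory markers had 5 of 6 higher (adjusted p = 2.3e-14, and 2.6e-04 with an estimated correlation). Reg4 rose from 13.9 ± 6.51 to 1358 ± 309.6 CPM (97.5-fold), the receptor kinase Kit from 8.34 ± 1.64 to 231 ± 8.01 (27.7-fold) and the growth factor Egf from 1.41 ± 0.142 to 38.4 ± 1.83 (27.1-fold).

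Absorptive and surface genes were lower in DC goblet cells. All 10 brush border genes fell (adjusted p = 4.2e-07, and adjusted p = 0.220 with an estimated correlation), as in the intermicrovillar cadherins Cdhr2 (5.35-fold) and Cdhr5 (4.91-fold). All 11 surface differentiation genes fell (adjusted p = 1.2e-14, and 0.00104 with an estimated correlation), including Emp1 (41.9-fold), Krt20 (15.0-fold), the transmembrane mucin Muc3 (11.3-fold) and Mxd1, an antagonist of Myc (7.15-fold). Colonocyte absorption had 10 of 13 lower and 3 higher (adjusted p = 1.5e-11, and 0.00110 with an estimated correlation); the carbonic anhydrases Car4 and Car1 fell 52.5-fold and 24.8-fold. Xenobiotic metabolism had 9 of 14 lower and 1 higher (adjusted p = 9.4e-09, and 0.0212 with an estimated correlation), with Cyp2c55 down 32.3-fold and the carboxylesterase Ces2e 13.8-fold. Fatty acid oxidation had 11 of 13 lower and 1 higher (adjusted p = 0.0108, and adjusted p = 0.379 with an estimated correlation). The small intestinal lists also fell, with 9 of 17 digestion genes lower and 1 higher (adjusted p = 1.5e-05, and 0.294 with an estimated correlation), 6 of 8 bile acid and cobalamin uptake genes lower (adjusted p = 0.00737, and 0.283) and 5 of 8 transcription factors lower (adjusted p = 0.00922, and 0.19). The peptide transporter Slc15a1 fell 45.2-fold and the intestinal alkaline phosphatase Alpi 42.0-fold.

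Immune and sensing genes were also lower in the DC goblet sort. MHC class II had 6 of 7 lower and 1 higher (adjusted p = 0.0108, and 0.379 with an estimated correlation), with H2-Aa at 0.225 ± 0.0562 CPM against 5.61 ± 1.25. Interferon response had 7 of 11 lower and 1 higher (adjusted p = 0.0162, and 0.533 with an estimated correlation), such as Ifit1 (14.6-fold) and Irf7 (5.04-fold). Microbial sensing had 10 of 16 lower and 1 higher (adjusted p = 9.9e-04, and 0.145 with an estimated correlation), including the inflammasome sensor Nlrp6 (4.49-fold) and the cytokine Il18 (4.37-fold). Enteroendocrine markers had 14 of 18 lower and 1 higher (adjusted p = 1.8e-05, and 0.294 with an estimated correlation), with the serotonin-synthesis enzyme Tph1 down 9.25-fold, and stromal markers had 3 of 4 lower (adjusted p = 0.0485, and 0.220 with an estimated correlation). Camera did not pass cholesterol synthesis (8 of 15 higher, 2 lower, adjusted p = 0.275), antimicrobial proteins (6 of 12 higher, 3 lower, 0.360), ion and fluid secretion (3 of 11 higher, 6 lower, 0.682) or posterior patterning (1 of 10 higher, 4 lower, 0.275). Nor did it pass stem cell (4 of 14 higher, 2 lower, 0.905), tuft (1 of 13 lower, 0.905), Paneth (2 of 9 higher, 0.394) or lymphocyte (7 of 13 lower, 0.147). It also did not pass B, plasma and myeloid (8 of 12 lower, 1 higher, 0.129), proliferation (1 of 21 higher, 0.394) or early response genes (2 of 16 higher, 0.938). The lymphocyte median was −2.86 as fitted and −1.47 with 4 genes at their bound. Ion and fluid secretion had a median of −0.43, a mean of 0.57 and an upward test. Adjusted over the list alone, the number of called genes was the same for each tested list except ion and fluid secretion (10 for 9), xenobiotic metabolism (12 for 10), microbial sensing (14 for 11), interferon response (9 for 8), small intestinal transcription factors (6 for 5), enteroendocrine (16 for 15), proliferation (0 for 1) and Paneth (1 for 2).

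**Figure D2:**
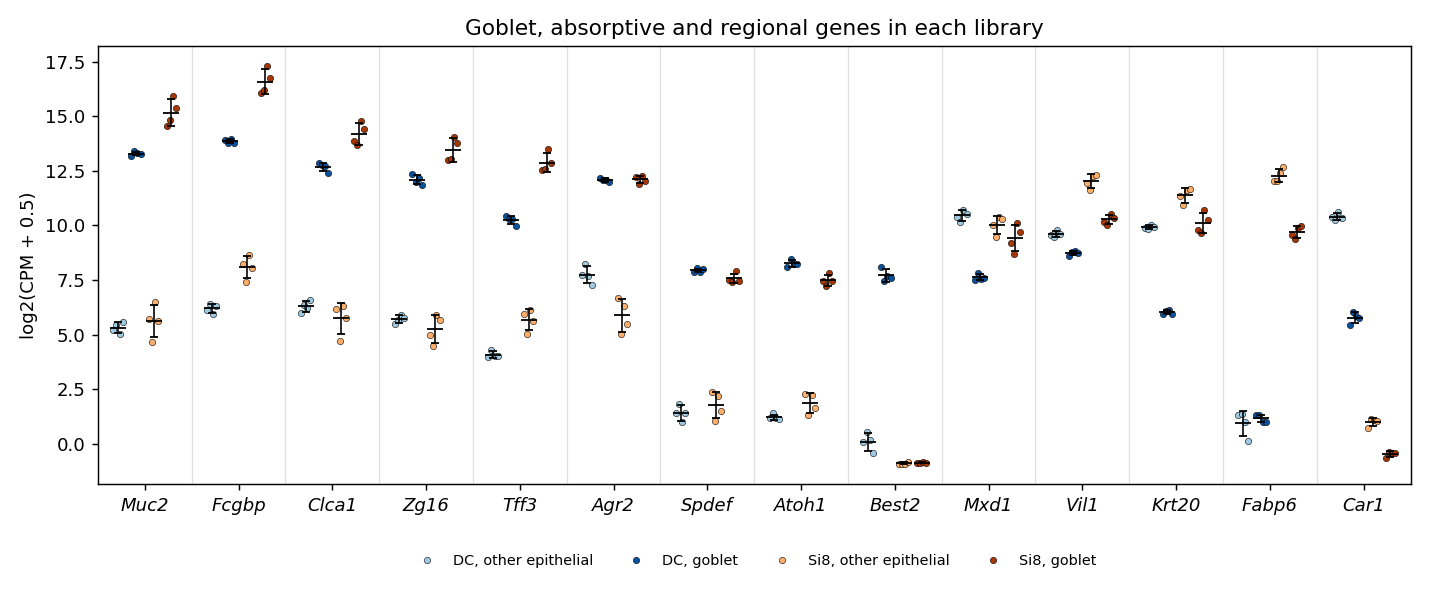
Levels of the genes fixed in advance in the 4 groups, as log2(CPM + 0.5); each point is a library and the bars are the mean and SD of 4 libraries. Fcgbp averages 14730.0 CPM in DC goblet and 104100.0 CPM in Si8 goblet cells, against 74.0 and 286 CPM in the other cells.

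In Si8, Muc2 and Fcgbp took a larger part of the goblet counts than in DC. Muc2 rose by 9.51 ± 0.45 (730.0-fold), and Fcgbp by 8.51 ± 0.35 (364-fold) to 104100.0 ± 42903 CPM. The vesicle-fusion ferlin Fer1l6 rose 469.9-fold and Frmd3, a membrane-skeleton protein, 450.1-fold, from 0.0880 ± 0.0545 to 40.3 ± 20.9 CPM. The apolipoproteins Apoa4 (24.9-fold) and Apoa1 (19.7-fold) and the ileal bile acid binding protein Fabp6 (6.01-fold) fell. The mast cell proteases Mcpt1 and Mcpt2 fell 321-fold and 258-fold, although reads of this near-identical pair cannot be assigned to 1 of them with certainty. edgeR called 10383 of 16001 genes, 5291 higher and 5092 lower in goblet cells, of which 1427 and 2321 changed by a log2 of at least 1.

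All 10 mucus components were again higher (adjusted p = 2.2e-18, and 0.00590 with an estimated correlation), with Clca1 up 337-fold, Zg16 291-fold, Tff3 146-fold and Agr2 68.9-fold. All 12 secretory transcription factors were higher (adjusted p = 2.3e-17, and 0.00590 with an estimated correlation), including Spdef (61.5-fold), Atoh1 (55.2-fold) and the ER-bound factor Creb3l4 (42.6-fold). Mucin O-glycosylation had 14 of 24 higher and 6 lower (adjusted p = 1.2e-06, and 0.124 with an estimated correlation), its median being 1.11 as fitted and 0.95 with 1 gene at its bound; Galnt5, which starts O-glycans, rose 71.3-fold. ER folding had 22 of 26 higher and 1 lower (adjusted p = 1.9e-06, and 0.174 with an estimated correlation), led by Ern2 (79.8-fold). ER to Golgi transport had 21 of 25 higher and 3 lower (adjusted p = 2.3e-07, and 0.219 with an estimated correlation), led by Kdelr3 (21.9-fold). Granule exocytosis had 10 of 17 higher and 5 lower (adjusted p = 5.9e-11, and 0.116 with an estimated correlation), including Sytl2 (115-fold). Deep crypt secretory markers had 5 of 6 higher (adjusted p = 4.4e-05, and 0.0133 with an estimated correlation), but Reg4 (7.06-fold) and Kit (6.88-fold) by smaller factors than in DC.

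All 9 Paneth cell genes were higher in the Si8 goblet sort (adjusted p = 1.1e-04, and adjusted p = 0.256 with an estimated correlation), with a median of 4.26. Mmp7, which processes defensins, rose 31.5-fold to 527 ± 71.9 CPM, and Defa24 rose 20.7-fold to 6949 ± 2708 CPM. Lectin Itln1, which Paneth and goblet cells both make, rose 23.0-fold to 3332 ± 1202 CPM. All 21 proliferation genes were higher (adjusted p = 0.0152, and adjusted p = 0.584 with an estimated correlation), at a median of 0.65, for example Ccnb1 (1.60-fold). Stem cell markers had 12 of 14 higher and 1 lower (adjusted p = 0.0173, and 0.429 with an estimated correlation), such as Ephb3 (2.43-fold) and Sox9 (2.17-fold).

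Absorptive genes of the ileum fell together. All 17 digestion and lipid absorption genes were lower (adjusted p = 1.9e-14, and 0.116 with an estimated correlation), as were all 8 genes of bile acid and cobalamin uptake (adjusted p = 7.0e-08, and 0.0607 with an estimated correlation), such as the cobalamin receptor Cubn (14.4-fold) and the bile acid carrier Slc10a2 (8.83-fold). All 10 brush border genes fell (adjusted p = 4.6e-07, and 0.217 with an estimated correlation), with Cdhr2 down 4.79-fold and Vil1, which bundles actin, 3.44-fold. Small intestinal transcription factors had 6 of 8 lower (adjusted p = 0.0114, and 0.217 with an estimated correlation), including Creb3l3 (22.3-fold). Xenobiotic metabolism had 11 of 14 lower and 1 higher (adjusted p = 2.1e-04, and 0.164), fatty acid oxidation 8 of 13 lower and 1 higher (0.0124, and 0.372) and cholesterol synthesis 12 of 15 lower (0.0328, and 0.568), the second of each pair being the adjusted p with an estimated correlation; Sqle, which epoxidises squalene, fell 2.01-fold. Surface differentiation had 2 of 11 higher and 5 lower and did not pass (adjusted p = 0.231): Emp1 fell 5.53-fold, whereas Guca2a, the precursor of guanylin, rose 4.94-fold.

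Markers of lymphocytes fell in the Si8 goblet sort, 13 of 13 (adjusted p = 1.6e-18, and 0.00590 with an estimated correlation), for example the granzyme Gzma (134 ± 23.2 to 6.06 ± 1.92 CPM, 22.2-fold). MHC class II fell in 7 of 7 (adjusted p = 9.1e-04, and 0.256 with an estimated correlation), with Cd74, the invariant chain, down 3.09-fold. Enteroendocrine markers fell in 16 of 18 (adjusted p = 3.0e-04, and 0.372), B, plasma and myeloid markers in 8 of 12 (0.0328, and 0.494) and stromal markers in 2 of 4 with 1 higher (0.0237, and 0.164), again with the second value from an estimated correlation. Camera did not pass tuft (8 of 13 lower, adjusted p = 0.231), interferon response (7 of 11 lower, 1 higher, 0.116), microbial sensing (7 of 16 lower, 3 higher, 0.228) or antimicrobial proteins (6 of 12 higher, 5 lower, 0.143). Nor did it pass early response (9 of 16 higher, 1 lower, 0.229), colonocyte absorption (5 of 13 lower, 2 higher, 0.235), posterior patterning (1 of 10 lower, 0.725) or ion and fluid secretion (5 of 11 higher, 3 lower, 0.805). It also did not pass the mitochondrially encoded genes (2 of 8 lower, 0.492). Ion and fluid secretion had a median of 0.48, a mean of −0.07 and an upward test. Adjusted over the list alone, the number of called genes was the same for each tested list except surface differentiation (8 for 7), tuft (9 for 8) and B, plasma and myeloid (9 for 8).

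**Figure D3:**
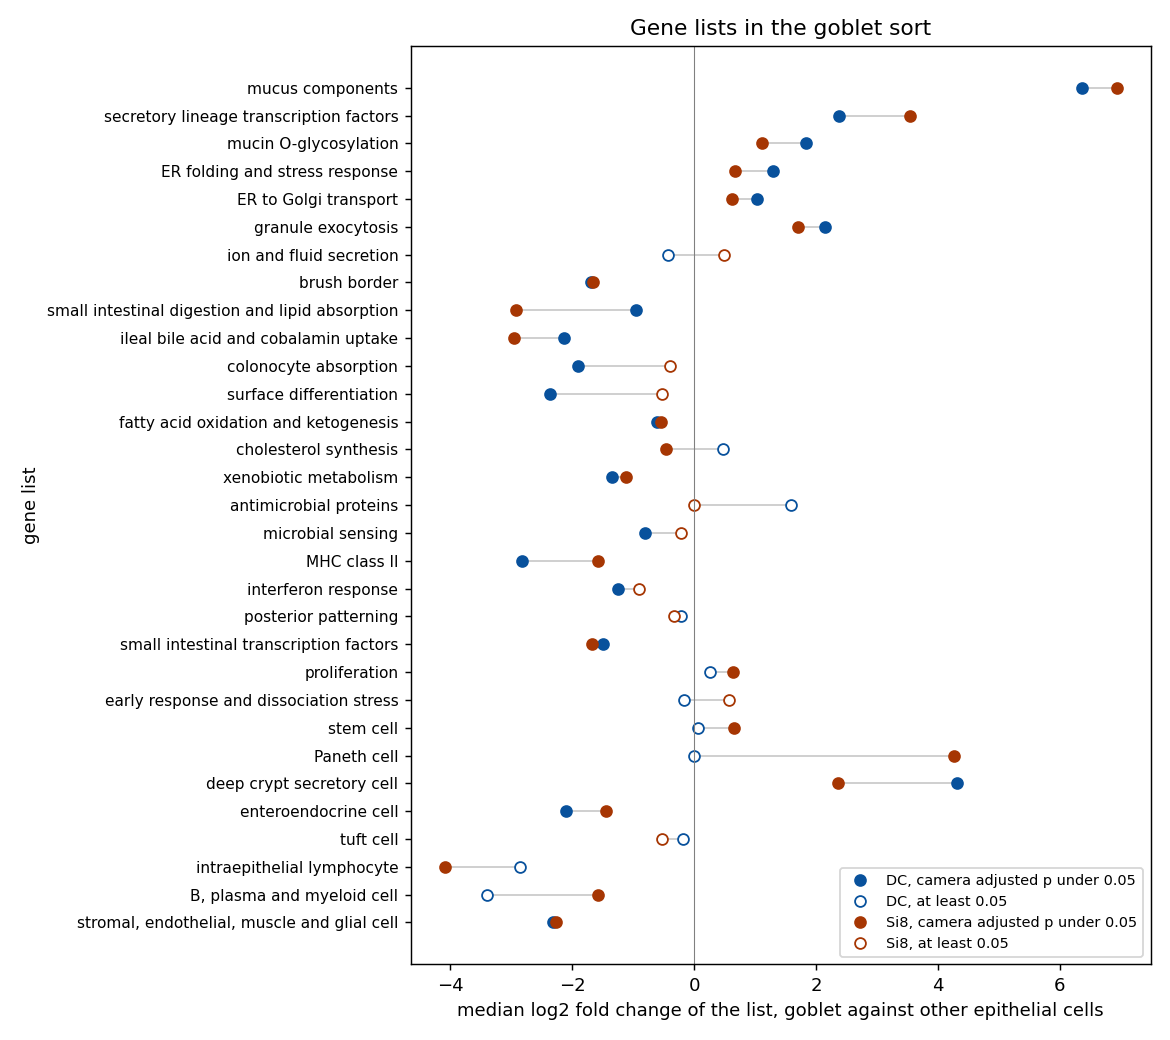
Median log2 fold change of each gene list in the comparisons of goblet with other cells in DC and in Si8; filled points passed camera at an adjusted p under 0.05 with the preset correlation. Mucus components have medians of 6.37 in DC and 6.94 in Si8.

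The goblet programmes of the 2 regions overlapped. 2975 genes were higher in goblet cells in both regions, against 1469 from independent lists of these sizes, and 2912 were lower in both, against 1422. 358 genes higher in DC goblet cells were lower in Si8 goblet cells, and 366 lower in DC were higher in Si8. Across the 16001 genes the DC and Si8 goblet effects had a Pearson r of 0.58 and a Spearman rho of 0.58; genes are not independent replicates, and the DC and Si8 comparisons share no library.

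The goblet sorts of the colon and of the small intestine differed in posterior patterning and antimicrobial genes. Hoxb13, a homeobox gene of the hindgut, stood at 264 ± 19.3 CPM in DC goblet cells, where Si8 goblet libraries together held at most 3 counts (ratio 37973, 95% counting interval 6815 to 1499850.0). Best2 was higher in DC by 11.78 ± 0.24, at 212 ± 43.7 against 0.0561 ± 0.00551 CPM. Nov, a matricellular protein, reached 1472 ± 169 CPM in DC goblet cells (ratio 70453, 95% counting interval 24108 to 341634). The antimicrobial lectins Reg3b and Reg3g were lower in DC by −13.92 ± 0.48 and −13.56 ± 0.48, and the Paneth cell gene Defa24 had 0 counts in DC goblet cells, at least 168149-fold lower. edgeR called 9943 of 16001 genes, 4902 higher and 5041 lower in DC; 2020 and 2101 changed by a log2 of at least 1. Higher genes were 49.3% of those called, and 73.9% when libraries were scaled by their totals alone, which shifted the median of all genes to 0.32. Region goes with library number and with the count table, so these cannot be told apart from region.

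All 10 posterior patterning genes were higher in DC goblet cells (adjusted p = 3.1e-35, and 1.7e-04 with an estimated correlation), among them Hoxa13 (ratio 3920.3, 95% counting interval 704 to 154844). Small intestinal transcription factors had 6 of 8 lower and 1 higher (adjusted p = 5.4e-04, and 0.0900 with an estimated correlation), with Gata5 down 301-fold. Of the mucus components 7 of 10 were lower in DC and 1 higher (camera adjusted p = 0.0323, and 0.558 with an estimated correlation). Muc2 fell 3.93-fold, Fcgbp 7.07-fold, Clca1 2.95-fold, Zg16 2.69-fold, Tff3 6.36-fold and Itln1 1239-fold. Agr2 did not pass (4345 ± 249 against 4429.9 ± 520.5 CPM, edgeR adjusted p = 0.93). Atoh1 was 1.71-fold higher in DC, whereas Spdef did not pass (246 ± 15.1 against 192 ± 31.9 CPM, adjusted p = 0.13) unless libraries were scaled by totals alone, only these groups were fitted or limma-voom was used (adjusted p = 0.00216, 0.00565 and 0.0316; from 0.00216 to 0.383 over all settings). Secretory transcription factors as a list did not pass (7 of 12 higher, 1 lower, adjusted p = 0.164), with Foxa2 3.43-fold higher and Bhlha15 2.89-fold lower. Mucin O-glycosylation did not pass either (14 of 24 higher, 6 lower, adjusted p = 0.174). Its members moved apart, B3gnt6 being 54.3-fold higher in DC while the sialyltransferase St3gal1 was 28.5-fold and the core 2 enzyme Gcnt4 19.6-fold lower. Outside the list, the blood group transferase Abo was at least 1765-fold higher and the galactosyltransferase B3galt2 2384-fold higher.

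Defence genes of the small intestine were low in the colon. The values below compare sorts, and cells carried over into the Si8 goblet sort, Paneth cells among them, were not excluded. That sort held the Paneth gene Lyz1 at 9392 ± 4462 CPM. Reg3b was higher in Si8 other cells (16806.5 CPM) than in Si8 goblet cells (7454 CPM), as was Apoa1 (3500 and 177 CPM). Antimicrobial proteins had 10 of 12 lower in DC goblet cells (adjusted p = 9.5e-09, and 0.00534 with an estimated correlation), and all 9 Paneth genes were lower (adjusted p = 8.6e-10, and 0.11 with an estimated correlation), their median being −13.71 as fitted and −12.42 with 5 genes at their bound. All 7 MHC class II genes were lower (adjusted p = 2.1e-17, and 0.0121 with an estimated correlation), with Cd74 at 0.785 ± 0.384 against 391 ± 63.4 CPM. Interferon response had 10 of 11 lower (adjusted p = 1.0e-04, and 0.339 with an estimated correlation), such as Ifit1 (14.1-fold). Digestion genes were lower in 16 of 17 (adjusted p = 9.8e-18, and 0.0689 with an estimated correlation). Bile acid and cobalamin uptake was lower in 8 of 8 (1.6e-15, and 0.00664 with an estimated correlation) and brush border in 9 of 10 (1.0e-04, and 0.349 with an estimated correlation). Apoa1 had a count ratio of 6437 (95% counting interval 1782 to 53151) and the disaccharidase Sis was 1578-fold lower. Colonocyte absorption had 9 of 13 higher and 1 lower (adjusted p = 4.0e-11, and 0.00387 with an estimated correlation), with the proton pump Atp12a 8351-fold and the carbonic anhydrase Car1 233-fold higher. Surface differentiation had 8 of 11 lower and 3 higher (adjusted p = 0.00960, and 0.162 with an estimated correlation), including Krt20 (17.7-fold).

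Crypt genes differed too. The stem cell list had 10 of 14 lower in DC goblet cells and 2 higher (adjusted p = 0.00244, and 0.349 with an estimated correlation), with Olfm4 at 0.0508 ± 0.0741 against 681 ± 202 CPM. Deep crypt secretory markers had 3 of 6 higher and 1 lower (adjusted p = 0.0374, and 0.129 with an estimated correlation; adjusted p = 0.0619 with library totals alone), with Reg4 12.6-fold and Kit 3.18-fold higher. Ion and fluid secretion had 4 of 11 higher and 4 lower (adjusted p = 0.00746, and 0.129 with an estimated correlation), including Car2 (1369.7-fold higher). Cholesterol synthesis had 10 of 15 higher and 2 lower (0.0443, and 0.655), tuft markers 9 of 13 lower (0.0374, and 0.655) and lymphocyte markers 11 of 13 lower and 1 higher (0.00278, and 0.349), the second being the adjusted p with an estimated correlation. The lymphocyte median was −3.50 as fitted and −3.01 with 4 genes at their bound. The mitochondrially encoded genes, 8 of 8 at 0 counts in DC, were lower (camera adjusted p = 5.7e-43, and 5.0e-04 with an estimated correlation). Their median was −15.21 as fitted and −12.12 at the bound, with mt-Co1 lower by at least 131675-fold. The count tables of the regions differ in these genes, so their test cannot show a regional difference. Camera did not pass ER folding (5 of 26 higher, 13 lower, adjusted p = 0.331), ER to Golgi transport (6 of 25 higher, 8 lower, 0.623), exocytosis (5 of 17 higher, 11 lower, 0.576) or fatty acid oxidation (8 of 13 higher, 3 lower, 0.199). Nor did it pass xenobiotic metabolism (5 of 14 higher, 7 lower, 0.772), microbial sensing (7 of 16 higher, 7 lower, 0.97), proliferation (12 of 21 lower, 0.0691) or early response (10 of 16 higher, 0.101). It also did not pass enteroendocrine (12 of 18 lower, 2 higher, 0.0553), B, plasma and myeloid (10 of 12 lower, 1 higher, 0.0987) or stromal markers (1 of 4 higher, 1 lower, 0.97); enteroendocrine and B, plasma and myeloid passed with library totals alone (adjusted p = 0.0104 and 0.0159). Xenobiotic metabolism had a median of −1.10 and a mean of 0.19 with a downward test, and microbial sensing a median of −0.20 and a mean of 0.13 with an upward test. Adjusted over the list alone, the number of called genes was the same for each tested list except cholesterol synthesis (14 for 12), xenobiotic metabolism (13 for 12), microbial sensing (15 for 14) and B, plasma and myeloid (12 for 11).

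The other epithelial cells differed between the regions as well. Tgm3, a transglutaminase, stood at 2265 ± 188 CPM in DC other cells against 0.0270 ± 0.0357 in Si8, and Aqp8 at 1015 ± 44.7 against 0.0330 ± 0.0265. Hoxb13 was at least 12048-fold higher in DC and the GPI-anchored Ly6g at least 4334-fold. In the other direction Apoa1 was 37510.3-fold lower in DC, Fabp6 3249-fold and the stem cell gene Olfm4 at least 11339-fold. edgeR called 10711 of 16001 genes, 5333 higher and 5378 lower in DC; 2592 and 2532 changed by a log2 of at least 1. Higher genes were 49.8% of those called and 66.5% with library totals alone, which shifted the median of all genes to 0.27. The region effects of the 2 cell types had a Pearson r of 0.82 and a Spearman rho of 0.72 across genes. They share no library, but in both of them region goes with library number and count table. The mitochondrially encoded genes are included. These correlations are therefore not independent evidence of a regional effect.

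Colonocyte absorption had 12 of 13 higher in DC other cells (adjusted p = 1.7e-20, and 2.5e-04 with an estimated correlation), with Car1 878-fold higher. Posterior patterning had 10 of 10 higher (adjusted p = 2.2e-27, and 2.2e-04 with an estimated correlation; median 9.23 as fitted and 8.11 with 2 genes at their bound). Surface differentiation had 6 of 11 higher and 2 lower (adjusted p = 0.00854, and 0.174 with an estimated correlation), such as Guca2a (5.86-fold) and the gasdermin Gsdmc4 (5.59-fold). Early response genes had 12 of 16 higher (0.0188, and 0.583 with an estimated correlation), such as Nr4a1 (19.4-fold). Ion and fluid secretion had 7 of 11 higher and 3 lower (0.0180, and 0.174 with an estimated correlation, and 0.0758 with library totals alone). Of the lists lower in DC, the first value is camera's adjusted p and the next the adjusted p with an estimated correlation. They were the digestion list (16 of 17, 2.2e-17, and 0.0708), bile acid and cobalamin uptake (8 of 8, 1.8e-15, and 0.0138), brush border (9 of 10, 7.0e-04, and 0.463), and small intestinal transcription factors (6 of 8, 1 higher, 0.00452, and 0.174). Also lower were antimicrobial proteins (10 of 12, 1 higher, 9.6e-06, and 0.0357), MHC class II (7 of 7, 1.2e-14, and 0.0257), and interferon response (9 of 11, 0.00629, and 0.518). Lower too were lymphocyte markers (13 of 13, 4.0e-13, and 0.0317), tuft markers (13 of 13, 0.0132, and 0.583), ER folding (19 of 26, 2 higher, 0.00520, and 0.463) and ER to Golgi transport (18 of 25, 3 higher, 7.0e-04, and 0.463).

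Paneth genes were lower in 9 of 9 in DC other cells (camera adjusted p = 6.4e-05, and 0.336 with an estimated correlation). Their median was −12.84 as fitted and −10.39 with 6 genes at their bound. Mitochondrially encoded genes were lower in 8 of 8, all at 0 counts in DC (camera adjusted p = 8.7e-33, and 0.00112 with an estimated correlation). Their median was −16.06 as fitted and −12.86 at the bound. The count tables of the regions differ in these genes, so their test cannot show a regional difference. Camera did not pass mucus components (2 of 10 higher, 4 lower, adjusted p = 0.825), secretory transcription factors (7 of 12 higher, 4 lower, 0.310), O-glycosylation (11 of 24 higher, 8 lower, 0.634) or exocytosis (9 of 17 higher, 6 lower, 0.518). Nor did it pass fatty acid oxidation (7 of 13 higher, 3 lower, 0.382), cholesterol synthesis (2 of 15 higher, 6 lower, 0.490), xenobiotic metabolism (6 of 14 higher, 7 lower, 0.371) or microbial sensing (8 of 16 higher, 6 lower, 0.205). It also did not pass proliferation (1 of 21 higher, 4 lower, 0.719), stem cell (6 of 14 higher, 4 lower, 0.392), deep crypt secretory (2 of 6 higher, 3 lower, 0.222) or enteroendocrine (4 of 18 higher, 9 lower, 0.338). The same holds for B, plasma and myeloid (8 of 12 lower, 0.0788, and 0.0238 with library totals alone) and stromal markers (3 of 4 higher, 1 lower, 0.980). Medians and tests differed in sign for O-glycosylation (median 0.33, mean −0.13, downward test), xenobiotic metabolism (median −0.39, mean 0.42, upward test) and stromal markers (median 1.47, mean 1.07, downward test). Adjusted over the list alone, the number of called genes was the same for each tested list except brush border (10 for 9), microbial sensing (15 for 14) and proliferation (2 for 5).

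The goblet effect itself differed between the regions, and the difference was tested directly. Most surface differentiation and colonocyte absorption genes had a lower goblet effect in DC. Guca2a fell in DC goblet cells (1010.1 ± 71.3 to 210.1 ± 17.9 CPM) and rose in Si8 (172 ± 22.4 to 852 ± 99.2), a difference of −4.57 ± 0.15, and Krt20 differed by −2.66 ± 0.26. The sodium channel subunit Scnn1a likewise fell in DC (175 ± 8.29 to 63.8 ± 5.48 CPM) and rose in Si8 (3.36 ± 0.595 to 42.6 ± 8.21), a difference of −5.13 ± 0.18. Gal3st2 and B3gnt6 moved the other way. Gal3st2 rose in DC (0.380 ± 0.0957 to 47.8 ± 9.14 CPM) and fell in Si8 (91.4 ± 14.5 to 31.8 ± 6.73), a difference of 8.47 ± 0.31. B3gnt6 differed by 7.73 ± 0.26. edgeR called 5133 of 16001 genes, 2492 with a goblet effect higher in DC and 2641 with one lower in DC; 1094 and 1322 differed by a log2 of at least 1. Of 100 splits of the 16 libraries, 6, the real one included, gave as many called genes; the 5 others keep the regions of one cell type apart, so they hold the regional difference.

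**Figure D4:**
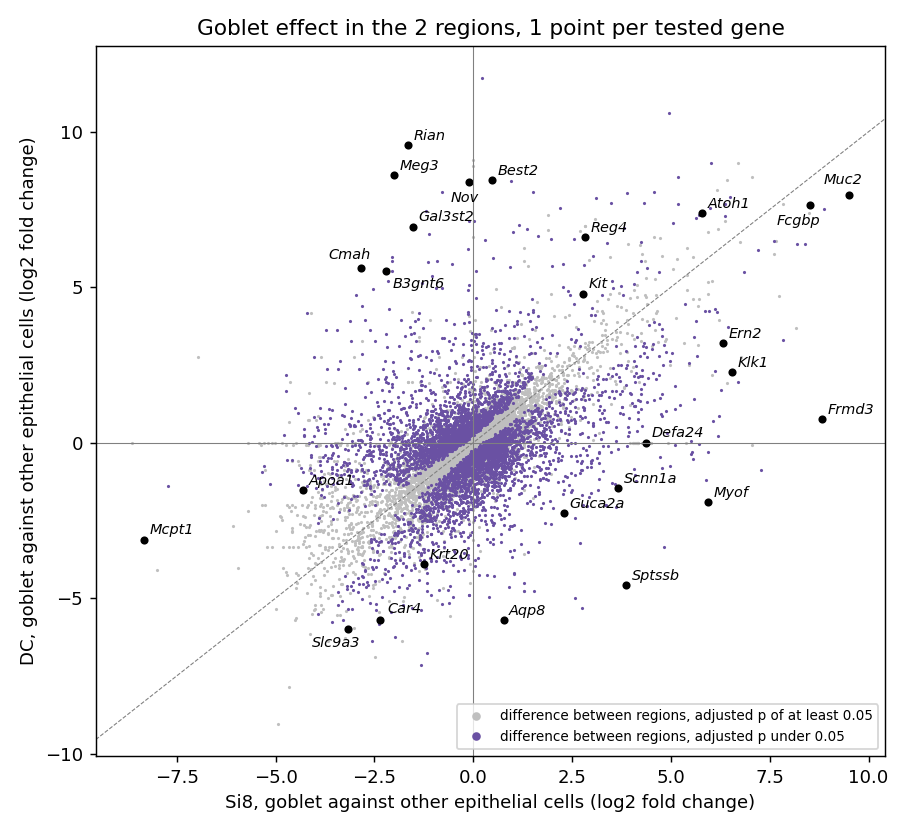
The log2 fold change of goblet against other cells in DC and in Si8 for 16001 genes, coloured by whether the difference of the effects passed an adjusted p under 0.05. 5133 genes passed, and the effects have a Pearson r of 0.58 across genes.

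Among lists, surface differentiation had 10 of 11 genes with a lower goblet effect in DC (adjusted p = 2.8e-17, and 0.00113 with an estimated correlation) and colonocyte absorption 8 of 13, with 2 higher (adjusted p = 7.6e-09, and 0.00513 with an estimated correlation, as in each later pair). Deep crypt secretory markers had 5 of 6 with a higher effect in DC and 1 lower (adjusted p = 4.6e-07, and 0.00477), including the Notch ligand Dll4 (3.99 ± 0.20), Reg4 (3.79 ± 0.45) and Kit (2.01 ± 0.17). Dll4 levels were close in the goblet sorts, at 45.5 ± 5.76 CPM in DC and 39.2 ± 4.63 CPM in Si8. They differed in the other cells, at 3.10 ± 0.328 CPM in DC and 42.5 ± 8.56 CPM in Si8. Mucus components had 6 of 10 with a lower goblet effect in DC (adjusted p = 0.00378, and 0.507), as in Clca1 (−2.02 ± 0.40) and the kallikrein Klk1 (−4.28 ± 0.22). Klk1 was nevertheless higher in DC goblet cells (2031 ± 134 CPM) than in Si8 goblet cells (434 ± 65.3 CPM). Its level in other cells was 423 ± 37.1 CPM in DC and 4.69 ± 1.35 CPM in Si8. Cholesterol synthesis had 13 of 15 higher in DC and 1 lower (adjusted p = 2.0e-05, and 0.507), for example the isomerase Idi1 (1.20 ± 0.16) and Sqle (1.19 ± 0.15). ER to Golgi transport had 18 of 25 higher and 1 lower (4.5e-07, and 0.507), ER folding 15 of 26 higher and 1 lower (8.3e-04, and 0.507), and O-glycosylation 8 of 24 higher and 6 lower (0.00683, and 0.507). Digestion genes had 5 of 17 higher and 3 lower (0.0143, and 0.867), and xenobiotic metabolism 8 of 14 lower and 2 higher (0.0142, and 0.507). Microbial sensing had 8 of 16 lower, with Nlrp6 at −1.27 ± 0.13 (0.0323, and 0.507), stem cell markers 9 of 14 lower and 2 higher, with Prom1 at −2.44 ± 0.14 (0.0323, and 0.726), and lymphocyte markers 4 of 13 higher (0.0385, and 0.705); with library totals alone these 3 lists gave 0.0950, 0.0977 and 0.0950.

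Camera did not pass the difference for secretory transcription factors (5 of 12 higher, 4 lower, adjusted p = 0.877), exocytosis (4 of 17 higher, 8 lower, 0.0647), ion and fluid secretion (3 of 11 higher, 5 lower, 0.662) or brush border (3 of 10 higher, 2 lower, 0.851). Nor did it pass bile acid and cobalamin uptake (1 of 8 higher, 0.320), fatty acid oxidation (1 of 13 higher, 3 lower, 0.877), antimicrobial proteins (2 of 12 higher, 1 lower, 0.877) or MHC class II (2 of 7 higher, 3 lower, 0.751). It also did not pass interferon response (4 of 11 lower, 0.255), posterior patterning (1 of 10 higher, 0.851), small intestinal transcription factors (1 of 8 higher, 2 lower, 0.662) or proliferation (3 of 21 lower, 0.125). The same holds for early response (3 of 16 higher, 7 lower, 0.196), Paneth (1 of 9 lower, 0.851), enteroendocrine (1 of 18 higher, 6 lower, 0.497) and tuft (0 of 13, 0.312). Further lists not passed were B, plasma and myeloid (0 of 12, 0.877) and stromal markers (1 of 4 higher, 0.952). Medians, means and tests differed in sign for ion and fluid secretion (−0.47, 0.63, downward) and fatty acid oxidation (0.11, −0.21, upward). They also differed for antimicrobial proteins (0.50, 0.69, downward), posterior patterning (−0.35, −0.32, upward) and stromal markers (−0.37, −1.15, upward). The mitochondrially encoded genes were at 0 in all DC libraries, so their difference has no meaning. Adjusted over the list alone, the number of called genes was the same for each tested list except mucus (7 for 6), secretory transcription factors (10 for 9), O-glycosylation (15 for 14), ER folding (19 for 16), exocytosis (13 for 12), colonocyte absorption (11 for 10), xenobiotic metabolism (11 for 10), microbial sensing (9 for 8), proliferation (0 for 3), Paneth (0 for 1) and stromal markers (2 for 1).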

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

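All tests reported in this part, apart from the difference of the goblet effect itself, were chosen only after the result was seen.

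The goblet effect differed between DC and Si8 in 5133 genes by the test of the difference. Imprinted noncoding RNAs of chromosome 12 rose in DC goblet cells alone, with differences (DC minus Si8, log2) of 11.49 for Mirg, 11.20 for Rian and 10.61 for Meg3; the Mirg value is a fitted one over 0 counts in DC other cells and few in Si8, so its size is uncertain. Nov differed by 8.49 (adjusted p = 0.0956 without Si8 other-cell replicate 3, and 0.062 with Si8 thinned to the DC depth), Cmah, which makes N-glycolylneuraminic acid, by 8.47, the sulfotransferase Gal3st2 by 8.47 and Best2 by 7.96, with Nov and Best2 near the floor in Si8. Sptssb, a subunit of the enzyme that starts sphingolipid synthesis, differed by −8.46, Ly6g by −8.09, Frmd3 by −8.06, Myof by −7.85, the lipase Mgll by −7.57 and Aqp8 by −6.47. Ly6g and Aqp8 are near the floor in Si8, Ly6g with 0 counts in other cells, so the sizes of their differences are uncertain. Among mucus genes the differences were −1.54 for Muc2, −2.02 for Clca1, −1.78 for Zg16, −0.997 for Tff3 and −1.80 for Agr2; with no filter Muc2 and Tff3 did not pass (adjusted p = 0.059 and 0.0827). Fcgbp, at −0.87, did not pass (adjusted p = 0.0704) but passed without DC other-cell replicate 12 (0.0498), Si8 other-cell replicate 5 (0.0237), Si8 goblet replicate 2 (0.0279) or Si8 goblet replicate 4 (0.0397). Differences of other genes were 1.59 for Atoh1, −2.27 for Mxd1, 0.91 for Vil1, −2.66 for Krt20, −1.92 for Car1 and 2.75 for Fabp6. Fabp6 was low in DC (1.54 CPM in other and 1.76 in goblet cells). In Si8 Car1 was low (1.53 CPM in other and 0.231 in goblet cells), as was Cmah (0.740 and 0.0990 CPM). The differences of Fabp6, Car1 and Cmah therefore rest on low levels in 1 region.

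Gene lists differed as well, by the test of the difference. Median differences were −1.48 for mucus components, 0.11 for O-glycosylation, 0.50 for ER folding, 0.56 for ER to Golgi transport, 1.51 for small intestinal digestion, −1.94 for colonocyte absorption and −2.03 for surface differentiation. They were 0.94 for cholesterol synthesis, −0.92 for xenobiotic metabolism, −0.48 for microbial sensing, −0.57 for stem cell, 1.76 for deep crypt secretory and 1.28 for lymphocyte markers. Lymphocyte markers were low in both DC sorts, with mean log2(CPM + 0.5) of −0.10 in other and −0.52 in goblet cells. Some colonocyte absorption genes were near the floor in Si8, such as Aqp8 (0.0330 CPM in other and 0.0561 in goblet cells). Others, such as Car4 (188 and 36.9 CPM), were not. Some digestion genes were near the floor in DC, such as Apoa1 (0.0906 and 0.0231 CPM), and others, such as Slc15a1 (323 and 7.27 CPM), were not. The median differences of these lists are therefore uncertain in size. Colonocyte absorption, surface differentiation and deep crypt secretory markers also passed with an estimated correlation.

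The count of splits does not exclude chance for the number of genes in the difference of effects: 6 of 100 splits of the 16 libraries, the real one included, gave as many as 5133, and the highest other gave 8964. The 5 other splits with as many genes keep the DC and Si8 libraries of one cell type wholly apart. In 4 of them those of the other cell type are apart too but for 1 library exchanged, on the opposite side, and in 1 they are mixed evenly, which points to the regional difference as a structure of the samples, so these splits do not measure chance alone. Smaller earlier draws of this kind also held splits as large. Splits that balance the regions on each side were added after this was seen, and 1 of 30 gave as many genes, the highest other giving 0; they cannot decide, because the regional difference inside each side fixes the outcome. For each of the 4 comparisons of groups only 1 of 35 splits was as large, the real one, which is the smallest share possible. The real split called 8911 genes against 1 at most in DC, and 10383 against 2123 in Si8. For region it called 9943 against 0 in goblet cells and 10711 against 0 in other cells. The 2123 came from exchanging libraries 3 and 6, and the cause was not tested. These splits argue against a random grouping of the libraries. They say nothing of chance between animals, which the labels do not give.

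The mitochondrially encoded genes were at 0 in the DC libraries and held 7.27% of counts in Si8 other cells and 3.75% in Si8 goblet cells. Nuclear genes of mitochondrial sequence held 3.17% of DC counts on average, 3.67% in other and 2.67% in goblet cells, and about 5.2e-04% in Si8. A different treatment of mitochondrial reads in the 2 count tables is a candidate explanation. Less mitochondrial RNA in DC cells as the whole cause is argued against, because these 15 nuclear genes were higher in DC in 15 of 15 (median log2 fold change 11.69, SD 3.40, goblet cells). No biological difference in mitochondrial RNA was tested beyond this.

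Paneth cell genes were higher in the Si8 goblet sort by a median log2 ratio of 4.26, which argues against free RNA of broken Paneth cells in both sorts. The ratios of the 9 genes had an SD of 0.29, as whole Paneth cells in the mCherry-positive gate would give. The limit for 1 shared ratio, set from the SE of these genes, was wide at 0.96. The Defa genes among them share reads, so their ratios are not independent. Goblet cells that carry these transcripts could share 1 ratio too, so both stay open. Defa24 stood at 6949 CPM and Lyz1 at 9392 CPM in this sort, and the gate on mCherry would remove Paneth cells that lack the reporter.

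Absorptive transcripts remained in both goblet sorts. Other cells carried over as the only source would leave 1 ratio for every gene. The log2 ratios had an SD of 0.88 over 25 genes in Si8 and of 2.02 over 10 genes in DC. The DC set held only the colonocyte absorption genes that were lower in the goblet sort. In Si8 the goblet level was 4.02% of the other-cell level for Apoa4 and 55.7% for Fabp1, and in DC 1.59% for Slc9a3 and 36.4% for Scnn1a; Fabp1 was chosen after its values were seen. Expression in goblet cells and carry-over of a subset of cells stay open.

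In 3 of 102 sets of 4 libraries 1 library lay far from the others, where chance gives about 5.1. Enteroendocrine markers averaged 1.63 in DC goblet replicate 11 against 1.41 to 1.43 in the others, tuft markers 1.76 in DC other-cell replicate 14 against 1.06 to 1.15, and B, plasma and myeloid markers 0.87 in Si8 goblet replicate 4 against −0.11 to −0.01.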

How the results depend on the processing

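4 alternatives were chosen after seeing the data (whole reads from the normalized signal, mitochondrial and matching nuclear genes left out, Si8 thinned to the mean DC total, Paneth genes and defensins left out). Of the counts of genes, 414 under other settings and 272 with 1 library left out stayed within 1.5 times. Library totals alone gave 7686 genes higher and 2711 lower in DC goblet cells against Si8, an adjusted p under 0.01 gave 1652 genes with a higher goblet effect in DC, and an absolute log2 of at least 1 gave overlaps of 775 higher and 1152 lower; the first follows from a shift of the median of all genes, and the others from the stricter threshold. With 1 library left out, called genes ranged from 8258 to 9012 in DC, from 9353 to 10407 in Si8, from 9284 to 9631 and from 10022 to 10622 for region in goblet and other cells, and from 4722 to 5459 for the difference of effects; genes higher in both regions ranged from 2546 to 3010 and lower in both from 2743 to 2898. Library totals alone moved the median of all genes in DC from 0.03 to 0.13. For region they moved it from −0.02 to 0.32 in goblet cells and from 0.0005 to 0.27 in other cells. No filter shifted it by 0.14 for the difference of effects. Among named genes, 60 values fell below and 18 rose past the threshold under other settings against 7665 the same, and 78 and 10 with 1 library left out against 4720. Among lists 74 fell below, 63 of them with an estimated correlation, 8 rose past and 809 were the same; no result reversed. Libraries with consecutive numbers correlated best, at 0.29 to 0.39 in Si8 and 0.07 to 0.26 in DC, though the labels do not say that these share an animal, and a block on them, run for the goblet comparisons and their difference, kept the 17 counts within 1.5 times, while 5 lists rose past the threshold (surface differentiation, interferon response and early response in Si8, proliferation and early response for the difference) and 3 fell below it (stromal markers in DC and in Si8, lymphocyte markers for the difference). With Si8 thinned, all 27 counts stayed within 1.5 times. Depth in DC limits genes near the floor. The causes were not tested further.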

Other observations

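The test on flanking genes was chosen before its result was seen, after the 3 RNAs had been noticed.

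Goblet cells of the colon carried a set of noncoding RNAs of an imprinted cluster. In DC goblet cells Rian reached 192 ± 9.46 CPM and Meg3 98.7 ± 6.80, against 0.250 ± 0.141 and 0.248 ± 0.0932 in DC other cells, 754-fold and 387-fold higher by edgeR (adjusted p = 9.7e-18 and 4.0e-17, n = 4 each). Mirg, a host of microRNAs, was at least 368-fold higher. Si8 goblet cells held 0.0992 ± 0.0708 CPM of Rian and 0.0962 ± 0.0438 of Meg3.

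Meg3, Rian and Mirg lie between 109452823 and 109749460 of chromosome 12, with Dlk1, whose difference was 7.82 and which was chosen after its values were seen. If a wider stretch shared the pattern, the flanking genes would follow, but the 13 tested genes within 1 Mb had a median difference of −0.015 (SD 0.78, from −2.46 to 0.21). The change may therefore be confined to the cluster among the genes tested, as a hypothesis.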
